A study of Pyrus x bretschneideri with 2 samples.

How the data were processed

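Total RNA from tissue around pear fruit wounds was made into Illumina TruSeq libraries, per the labels' protocols, 1 from fruit treated with sterile distilled water and 1 from fruit treated with Meyerozyma guilliermondii. The authors deposited a table of FPKM values for 45022 genes in both libraries, 41200 with Pbr identifiers and 3822 with XLOC identifiers of assembled loci. They also deposited a table of their comparison, which holds 381 genes, each with a log2 fold change of the yeast over the water library, per the file headers. The p-values of that table are adjusted (FDR), per the file headers, and were deposited for the 381 genes only. Bowtie 0.12.2 is named, per the submitters' processing notes. The gene counter, the genome build, the annotation, the comparison tool and any scaling between the libraries are not given in the sources used here. Columns were assigned to groups through the sample titles. No coordinates are printed, since the reference gene table at hand does not carry the Pbr or XLOC identifiers and was not used.

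With 1 library per group no test, standard deviation or p-value was computed. Ratios were log2((yeast + 1)/(water + 1)) on the FPKM values, with a pseudocount of 1, over genes with at least 1 FPKM in either library, and a 2-fold size rule took the place of a test. FPKM ratios without the pseudocount were compared with the authors' deposited log2 values to check their direction. A gene at exactly 0 FPKM is described as listed at 0 and is given no fold unless whole reads were implied as below, since such a 0 can be a failed estimate: 3 genes called by the authors have 0 FPKM in both libraries.

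The choices of size rule, filter, pseudocount, alternatives and 47 gene lists were made before the data were examined. The lists were matched by text patterns to the deposited protein descriptions (the best database hit, Swiss-Prot and Pfam, with organism names removed). As only called genes have descriptions, each list is given as its called members higher and lower beside the split of all called genes, with an exact (Clopper-Pearson) 95% binomial interval that describes genes and not replicates, and the planned comparison with random lists of matched expression was not possible. A median log2 ratio is given for lists with at least 5 called members of at least 1 FPKM and describes these members alone. Some patterns caught other genes through shared domain names, and not all of these are named with the list. A pattern can also miss a member: XLOC_012917, described as 4-hydroxycoumarin synthase 1-like, fell outside the biphenyl list.

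Named genes followed a rule: among genes with at least 5 FPKM in either library and an informative description, the 15 highest and 15 lowest ratios, and per list the 2 highest and 2 lowest members with at least 1 FPKM and the most abundant one. All other genes were named after their values were seen, among them further members of the lists, the CYP84A1-like and CYP94C1-like genes, Pbr025676 and Pbr039194 (outside the auxin list), genes with fungal hits and uncharacterized XLOC loci. Multigene families with near-identical members (flavonol synthase 3-like, peroxidase N1-like, PR10, biphenyl synthases) can share reads, and how the authors' counting split these is not known here.

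Sequencing depth is not in the files. Its ratio between the libraries was estimated in 2 ways. The commonest log2 ratio of the FPKM values of 2985 genes below 0.5 FPKM and above 0 in both libraries, where 1 read against 1 read is frequent, was 0.069, shared by 56 genes. For genes listed at 0 in the library where the authors called them lower (the 3 genes at 0 in both libraries included, XLOC_032966 left out), the authors' deposited log2 values fell on steps of whole reads within a tolerance of 0.001 for 65 of 84 genes at 0 in the yeast library and 21 of 40 at 0 in the water library, and the ratio of the steps was 1.05. The tolerance was narrowed and the step fitted more finely after the first values were seen. The fewest whole reads behind such a call were 23, a minimum set by a cut-off, since only larger deposited values were matched to the steps. Genes with values below the cut-off counted as off the steps whatever their fit. A step was taken as 1 read, the largest unit that fits, and a gene on the steps was given a lower bound of its fold against a floor of 3 reads in the library where it was at 0.

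The size rule was tested on simulated data: reads were drawn for the 45022 genes at 48.8 reads per FPKM with counting error only, and 200 genes were changed. Of 50 genes per size, 10.0% of those changed 2-fold passed the 2-fold rule, against 96.0% of those changed 4-fold, 96.0% changed 8-fold and 96.0% changed 16-fold, and 0 of 21815 unchanged genes passed. With the pseudocount an exact 2-fold change always falls short of the 2-fold rule. The 10.0% therefore passed through counting error, and the rule misses such a change for most genes by construction. Counting error alone is not the spread between fruit. The same rate was used for all genes, the median over called genes with whole reads as above. Reads per FPKM differ between genes, such as 299 reads at 23.3 FPKM for Pbr025260 and 24 reads at 0.0822 FPKM for Pbr004541. Genes with fewer reads per FPKM vary more than simulated, so the count of 0 does not cover them. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, 3 rescalings of the libraries, a 4-fold size rule, a stricter threshold on the authors' calls, and sets of called genes without low, 0-listed or other loci. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.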

Results

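RNA was sequenced from the tissue around wounds of pear fruit (Pyrus x bretschneideri). The wounds had received either sterile distilled water, as the control, or cells of the yeast Meyerozyma guilliermondii, a species studied as a biological control agent against fruit rots. The fruit were then kept for 3 days at 20 °C. Each group held 1 library, named here the water library and the yeast library, so no difference below has a replicate check. The deposited FPKM values (fragments per kilobase of gene, scaled to library size) covered 45022 genes and summed to 692635 in the water library and 748043 in the yeast library. A level of at least 1 FPKM was reached by 21484 genes in the water library and by 21495 in the yeast library. Read totals were not among the values used here. The values that low genes shared put the water library at 1.05 times the depth of the yeast library.

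The comparison of the 2 libraries asks which pear transcripts around a wound differ between fruit given the yeast and fruit given water. Of 12 called genes of the phenylpropanoid and lignin list, 8 were higher in the yeast library and 4 lower, a share whose interval includes that of all called genes. The higher ones included a cinnamyl alcohol dehydrogenase 1 gene (Pbr026289, 0.342 FPKM with water and 19.7 with the yeast) and a shikimate O-hydroxycinnamoyltransferase gene (Pbr022425, 8.75 and 78.3). The major allergen gene Pyr c 1 (Pbr012008), of the PR10 family of pathogenesis-related proteins, was the most abundant of the genes called higher, at 330.0 FPKM with water and 2162 with the yeast. Lower in the yeast library were all 8 called genes of the list of jasmonate synthesis and its JAZ repressors, all 6 of calcium signalling, all 5 of biphenyl synthesis and all 4 of pectin degradation. None of the 4 is set clearly apart from all called genes: the jasmonate interval ends at 36.9% higher beside a share of 37.5%, and without genes listed at 0 only 5 of its called genes are left, all lower. With at least 5 FPKM in either library 3 jasmonate genes are left, and without genes listed at 0 there are 3 calcium genes, all lower. Members that were not called carry no description and were not counted. The 3,5-dihydroxybiphenyl synthase-like gene Pbr027910 stood at 47.8 FPKM with water and 1.45 with the yeast, and the TIFY 10B-like gene Pbr039229 at 23.9 and 0.814.

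Most genes lay close together in the 2 libraries. Among 22603 genes with at least 1 FPKM in either library, 750 (3.32%) were at least 2-fold higher in the yeast library on the log2(FPKM + 1) scale, 678 (3.00%) were at least 2-fold lower, and 21175 (93.7%) lay within 2-fold. At 4-fold the balance turned, with 144 genes higher and 194 lower. The scale understates differences of low genes. The authors' deposited table lists 381 genes as different, 143 higher (37.5%) and 238 lower in the yeast library, with adjusted p-values of at most 0.00994 and absolute log2 fold changes of at least 2.66. That test compares these 2 libraries and not the treatments. The gene groups below are counted among those 381 genes, the ones that carry a description in the files, and their shares stand beside the 37.5% of all called genes, with exact 95% binomial intervals over genes, which are not replicates.

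**Figure D1:**
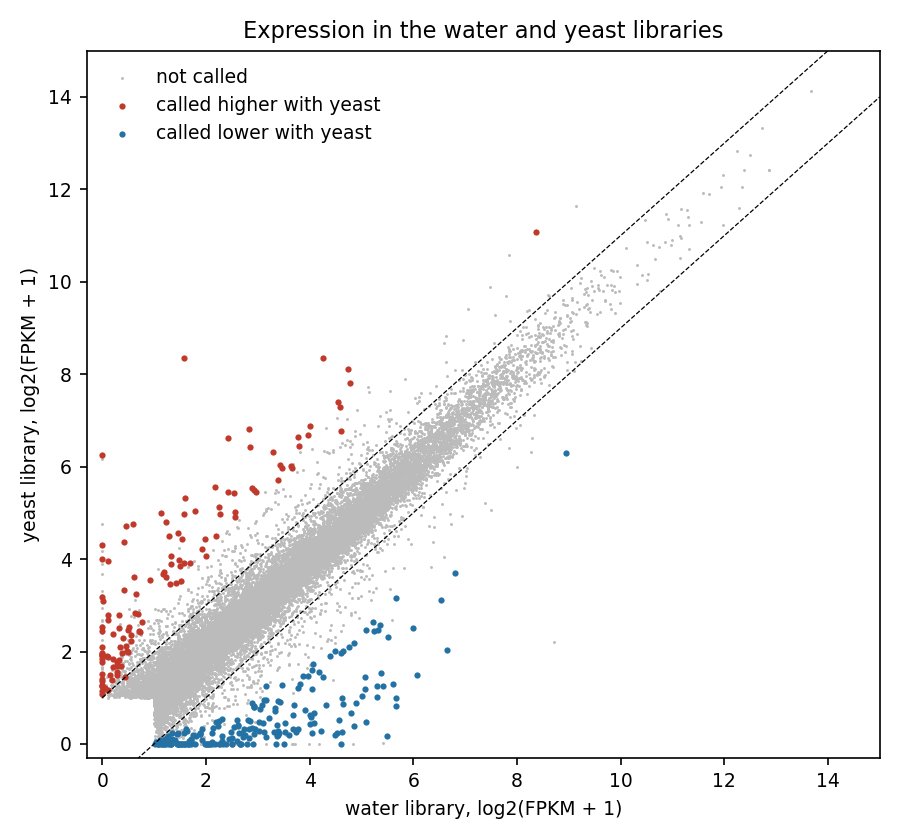
Level of each gene with at least 1 FPKM in either library, as log2(FPKM + 1), in the water library (horizontal axis) and the yeast library (vertical axis); each point is a gene, red and blue mark the 319 genes of this level called higher or lower in the authors' deposited table, and the dashed lines mark a 2-fold difference. Of 22603 genes, 21175 lie between the lines.

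The phenylpropanoid and lignin list had 12 called genes, 8 higher and 4 lower (66.7% higher, interval 34.9% to 90.1%). Beside the dehydrogenase and the transferase above, the higher members were a caffeic acid 3-O-methyltransferase (Pbr013510, 12.7 FPKM with water and 98.3 with the yeast), a caffeoyl-CoA O-methyltransferase (Pbr038709, 10.1 and 61.9), 4-coumarate--CoA ligase 2-like genes (Pbr024635, 0.161 and 2.58, and Pbr001283, 0.412 and 3.00), a further cinnamyl alcohol dehydrogenase 1 gene (Pbr026287, 0.694 and 5.20) and laccase-15-like (Pbr013454, 0.359 and 1.73). These enzymes act in sequence in making and polymerising monolignols, the building blocks of lignin. In the authors' deposited table their log2 fold changes ran from 2.66 for Pbr038709 to 5.74 for Pbr026289. The lower members were laccase-7-like genes, led by Pbr035929 (28.7 and 0.852), and a caffeic acid 3-O-methyltransferase-like gene (Pbr025883, 49.6 and 7.89) whose other deposited description is anthranilate N-methyltransferase. A pair of CYP84A1-like genes, of the ferulate 5-hydroxylase family of syringyl lignin synthesis, was also higher (Pbr022142, 1.52 and 15.8; Pbr029428, 0.0640 and 2.76).

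The jasmonate list had 8 called genes, 0 higher and 8 lower (0% higher, interval up to 36.9%). They were allene oxide synthase genes (Pbr006205, 6.56 FPKM with water and 0.780 with the yeast; Pbr006204, 2.72 and 0.155), allene oxide cyclase 4 (Pbr030638, 1.51 and listed at 0), a 13S-lipoxygenase gene (Pbr004541, 0.0822 and listed at 0) and the JAZ-type genes TIFY 9 (Pbr003675, 7.29 and 0.691), TIFY 10A (Pbr027730, 3.32 and 0.182) and TIFY 10B (Pbr039229, above, and Pbr040357, 1.98 and listed at 0). The synthase, cyclase and lipoxygenase make jasmonate, and JAZ proteins are repressors whose genes are themselves switched on by it. Over the 7 called members with at least 1 FPKM the median log2 ratio was -1.87. MYC2-like (Pbr037113), the main transcription factor of the jasmonate response, was lower too, at 11.8 and 0.533, as were CYP94C1-like genes, of the family that oxidises active jasmonate (Pbr002629, 3.33 and 0.0230).

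**Figure D2:**
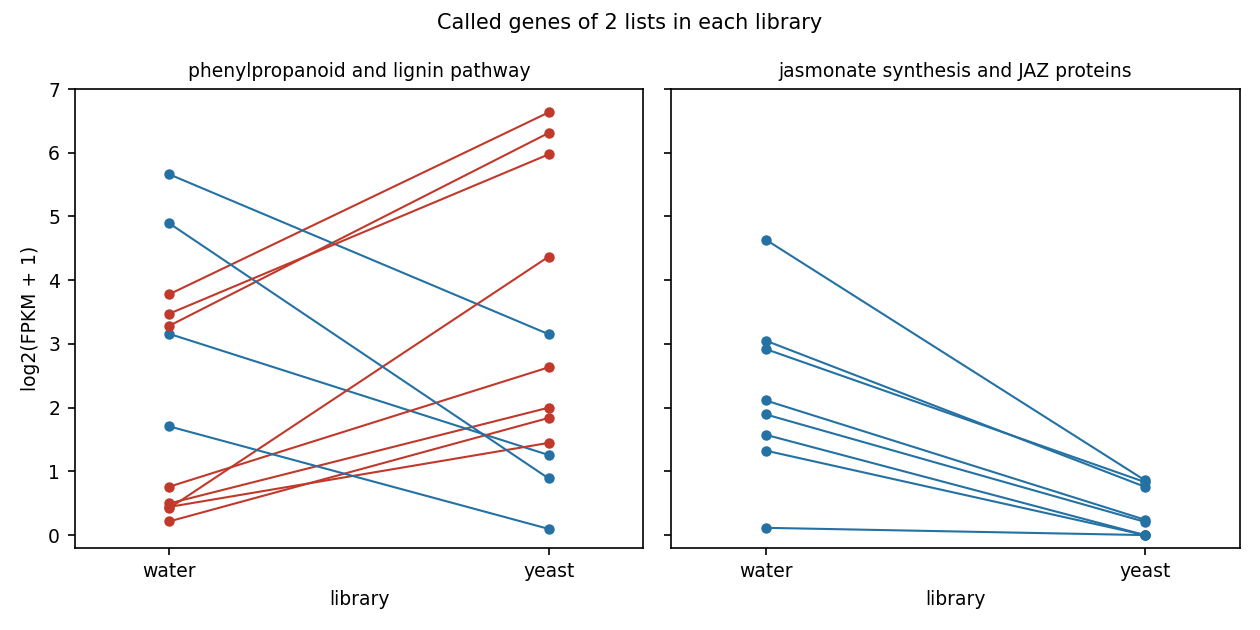
Level of the called genes of the phenylpropanoid and lignin list (left, 12 genes) and of the jasmonate list (right, 8 genes) in the water and yeast libraries, as log2(FPKM + 1); each line joins the values of 1 gene, red where the gene was called higher and blue where it was called lower in the authors' deposited table. In the left panel 8 lines go up and 4 go down, and in the right panel 8 go down.

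The calcium signalling list had 6 called genes, 0 higher and 6 lower (interval up to 45.9% higher), among them CML42-like genes (Pbr028492, 12.7 FPKM with water and 1.30 with the yeast; Pbr013669, 8.35 and 0.472), CML44 (Pbr027922, 6.50 and listed at 0) and calcium-dependent protein kinase 26-like (Pbr001322, 6.64 and 0.743). The receptor-like kinase list had 6 higher and 8 lower, but 2 of the higher ones are described as receptor-like protein 2 and not as kinases (XLOC_004778, 0.647 and 4.33; XLOC_005967, 0.222 and 2.41). The kinase At1g11050-like gene Pbr017074 (21.4 and 0.151) was lower, and Pbr000076, described as the proline-rich kinase PERK10 by 1 of its annotations, was listed at 0 with water and at 18.9 FPKM with the yeast. Called members of the ethylene list were 1 higher and 3 lower. The lower ones included 1-aminocyclopropane-1-carboxylate synthase genes, which make the ethylene precursor (Pbr036692, 15.2 and 0.504; Pbr002233, 3.72 and 0.305). The abscisic acid list gave a pair of genes, both lower, described as probable protein phosphatase 2C 34 (Pbr028950, 4.86 and 0.289) and 2C 25 (Pbr010918, 2.69 and 0.167). A role of this pair in abscisic acid signalling was not shown. The auxin list had 1 called gene, ARG7-like, which was higher (Pbr026939, 1.78 and 14.8). Outside its patterns, a tryptophan aminotransferase-related gene (Pbr025676, 33.1 and 4.54) and the IAA-amino acid hydrolase gene ILR1-like 4 (Pbr039194, 2.79 and 0.0540) were lower. A mitogen-activated protein kinase kinase kinase 3-like gene was lower (Pbr035710, 4.63 and 0.193).

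WRKY genes were 3 higher and 2 lower, but 0 higher and 1 lower among genes with at least 5 FPKM in either library, and 1 higher and 2 lower without genes listed at 0. WRKY31-like genes were higher (Pbr039741, 0.372 FPKM with water and 3.32 with the yeast; Pbr023691, listed at 0 and 2.43), and WRKY40 (Pbr022408, 7.92 and 0.924) and WRKY75 (Pbr037452, 2.81 and 0.243), both known from plant defence, were lower. The ERF and AP2 list was 3 higher and 6 lower. ERF113-like (Pbr037846, 4.86 and 42.4) and ERF114-like (Pbr010139, 1.90 and 20.6) were higher, while ERF1B-like (Pbr023044, 18.9 and 0.802), of the family that answers to ethylene and jasmonate, and ERF098-like (Pbr011103, 2.26 and listed at 0) were lower. Among genes with at least 5 FPKM in either library, this list had 2 higher and 1 lower. The 3 called NAC genes were lower, all described as NAM-1-like, the most abundant being Pbr021868 (1.91 and listed at 0). The others, Pbr000586 and Pbr037179, had identical values (0.310 and listed at 0) and may share reads, so they may not be separate genes. The MYB list, 1 higher and 3 lower, held MYC2-like through a shared domain name, Myb4-like genes on the lower side (Pbr025360, 17.1 and 1.94) and an At1g14600-like gene on the higher side (Pbr012187, 0.309 and 2.91).

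The list for biphenyl phytoalexins, the antimicrobial compounds of apple and pear relatives, had 5 called genes, 0 higher and 5 lower (interval up to 52.2% higher), with a median log2 ratio of -4.27. The 4-hydroxycoumarin synthase 2 gene Pbr027907, from the same enzyme family, had 44.0 FPKM with water and 0.128 with the yeast, the lowest ratio of the named genes, and a log2 fold change of -8.31 in the authors' deposited table. Pbr027917 stood at 38.3 and 1.03, Pbr021494 at 2.01 and listed at 0, and Pbr027912 at 1.33 and 0.0759. The flavonoid list was 1 higher and 16 lower (5.88% higher, interval 0.149% to 28.7%). But 5 of its lower members are those same synthases, matched through a shared domain name, and no interval was computed without them. Most of the others were flavonol synthase 3-like genes (Pbr003486, 38.6 and 1.40; Pbr003484, 32.4 and 1.28; Pbr003485, 31.3 and 1.06), neighbours by identifier that may share reads, so their values are uncertain as separate genes. The bifunctional dihydroflavonol 4-reductase-like gene Pbr005931 was the higher member (0.151 and 2.17).

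PR10 genes were divided, 3 higher and 2 lower, and 2 each way without genes listed at 0 or at 5 FPKM. Beside Pyr c 1, the Pru ar 1-like gene Pbr040353 was higher (6.77 FPKM with water and 42.6 with the yeast), as was Pbr012004, whose level with the yeast was only 0.0305 FPKM. The Pru ar 1-like genes Pbr042268 (50.1 and 0.772) and Pbr012011 (50.1 and 0.988) were lower. These near copies may share reads too. Thaumatin-like protein 1a (PR5, Pbr032573) is called lower in the authors' deposited table although the FPKM values list it at 0 in both libraries. The lists of PR1, beta-1,3-glucanases, chitinases, defensins and lipid transfer proteins, and the salicylate pathway had 0 called genes.

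**Figure D3:**
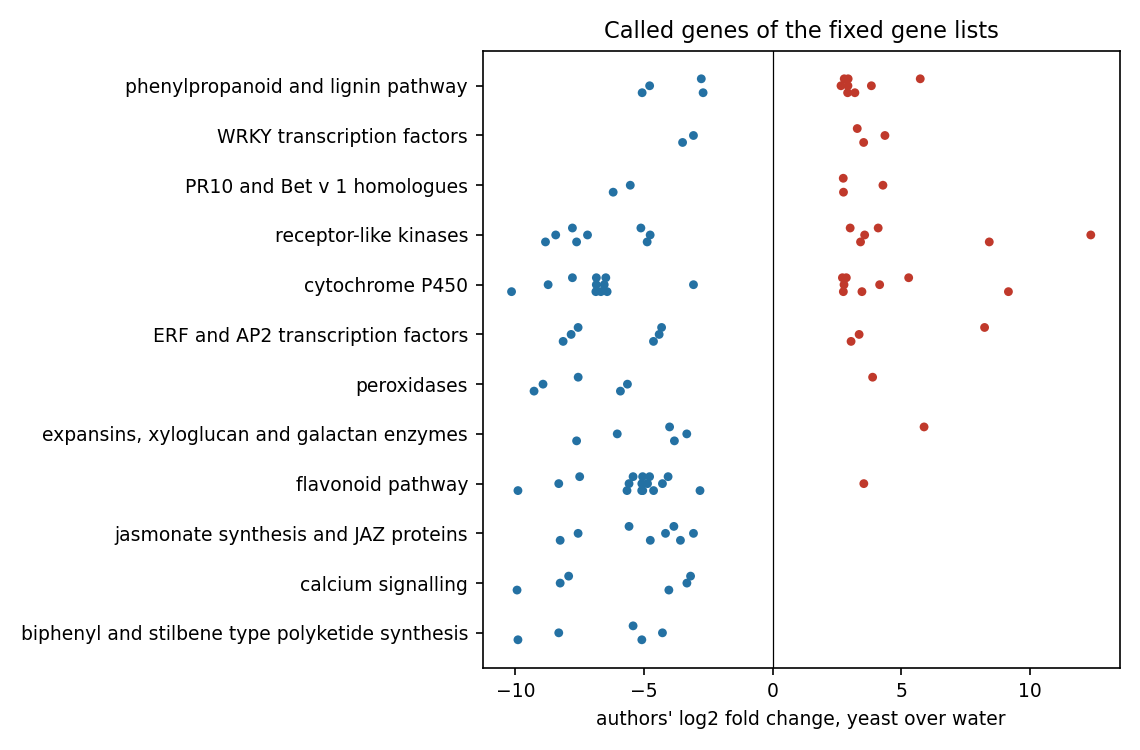
Log2 fold change, yeast over water, of each called gene in 12 gene lists, from the authors' deposited table; each point is a gene, red above 0 and blue below 0, and points are offset vertically so that they can be seen apart. The jasmonate, calcium and biphenyl lists have points on the lower side only. Values of genes listed at 0 in a library that fell on steps of whole reads depend on how the authors' test treats a 0. They are no measure of size. Over all called genes, 19 of 84 listed at 0 in the yeast library and 19 of 40 in the water library were off these steps. For these the FPKM value of 0 may be a failed estimate, and the size is uncertain.

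The polyphenol oxidase list was 0 higher and 2 lower. Polyphenol oxidase Pbr000321, an enzyme of tissue browning, stood at 495 FPKM with water and 77.8 with the yeast, and XLOC_029389, of the same name, at 5.34 and listed at 0. Peroxidases were 1 higher and 5 lower (16.7% higher, interval 0.421% to 64.1%), with a median log2 ratio of -2.07. Cationic peroxidase 1-like was higher (Pbr015965, 1.99 and 30.5), and peroxidase A2-like (Pbr000687, 22.8 and 0.425) and a peroxidase N1-like cluster (Pbr026503, 7.96 and 0.105) were lower. Glutathione S-transferase U8-like was lower (Pbr020346, 7.52 and 0.802). Cytochrome P450 genes were 8 higher and 11 lower, with a median log2 ratio of -1.46. The lower ones included cytokinin hydroxylase-like genes (Pbr031329, 28.0 and 0.309; Pbr031328, 22.0 and 0.187) and a CYP749A22-like gene (Pbr030004, 23.7 and 0.193). Of the 8 higher, 6 carry only the description cytochrome P450 like_TBP, from hits in other plant families, and without these the split was 2 higher and 11 lower. Among members with at least 5 FPKM the median log2 ratio of this list was 2.01, the opposite sign, with 7 higher and 6 lower left. All 6 loci with the like_TBP description are among these 7, so the change of sign rests on them. The respiratory burst oxidase list had 0 called genes.

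The pectin degradation list was 0 higher and 4 lower (interval up to 60.2% higher): pectinesterase 2-like genes (Pbr015755, 32.7 FPKM with water and 1.71 with the yeast; Pbr012741, 0.794 with the yeast) and polygalacturonase QRT3-like genes (Pbr023154, 12.4 and 0.191; Pbr031597, 1.76 and 0.180). Expansins and xyloglucan enzymes were 1 higher and 5 lower (interval 0.421% to 64.1% higher), all at low levels, with the KATAMARI1-like galactosyltransferase gene Pbr030809 at 2.70 and 0.179. The cellulose synthesis list was 3 higher and 0 lower (interval from 29.2% higher). It held 2 cellulose synthase-like H1 genes (Pbr018127, 0.573 and 8.41; Pbr041814, listed at 0 and 1.11) and Pbr018125, whose best hit is a pentatricopeptide repeat protein and which the FPKM values list at 0 in both libraries. The polygalacturonase inhibitor list had 0 called genes.

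Further genes among the 15 highest and 15 lowest ratios belonged to no list above. On the higher side were the yippee-like gene Pbr013545 (4.38 FPKM with water and 97.1 with the yeast), SULFUR DEFICIENCY-INDUCED 1 genes, named for their induction under sulphur shortage (Pbr033006, 0.503 and 26.1; Pbr026169, 6.18 and 84.4; Pbr026168, 0.0847 and 14.5), WAT1-related genes (Pbr037705, 3.55 and 46.4) and a BURP domain gene (Pbr017157, 2.48 and 32.0). On the lower side were the EP1-like glycoprotein gene Pbr038207 (98.9 and 3.09), VQ motif-containing protein 10 (Pbr025260, 23.3 and listed at 0), a 1,4-dihydroxy-2-naphthoyl-CoA thioesterase gene (Pbr018580, 66.3 and 1.82) and an AOP2-like dioxygenase gene (Pbr003836, 41.6 and 1.40).

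The remaining lists gave few calls. The hypoxia and the aroma lists shared the same 5 genes, 3 higher and 2 lower, and these were the cinnamyl alcohol dehydrogenases above, a furanone reductase-like gene, a mannitol dehydrogenase and a quinone oxidoreductase, not fermentation enzymes. The sugar list held only the pectinesterases above, the antioxidant list only a 5'-adenylylsulfate reductase gene (Pbr039726, listed at 0 and 0.813), and the disease resistance list only RPM1-like (Pbr016327, 0.0461 and 0.622). The senescence list was 3 higher, with XLOC_031499 (18.1 and 328) as its most abundant member, described from pea as a putative senescence-associated protein. The protease inhibitor list had 1 higher gene, and the seed list 1 higher and 2 lower, the latter with a late embryogenesis domain (Pbr010833, 26.9 and 0.581). The lists for photosynthesis, cuticle and epidermis, phloem and xylem, ribosomal proteins, histones, heat shock proteins, terpenoids and gibberellin had 0 called genes. The epidermis patterns did not match the EP1-like genes, described as epidermis-specific, of which 3 were called, all lower (Pbr038207, above; Pbr038206, 91.5 and 7.68; Pbr038209, 17.6 and 0.224).

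The calls higher and lower differed in their share of best hits outside pear, apple and Prunus. Such a hit does not by itself show RNA of another organism. Of the 143 genes called higher, 37 (25.9%, interval 18.9% to 33.9%) had their best protein hit outside pear, apple and Prunus, against 7 of the 238 called lower (2.94%, interval 1.19% to 5.97%), and without these genes 106 higher and 231 lower were left, a count chosen after seeing the data. They include the 6 P450-like loci and XLOC_031499. The fixed list of fungal hits had 1 called gene, higher with the yeast (Pbr024253, 0.466 and 4.13). In the yeast genera searched, Meyerozyma, Candida and Saccharomyces among them, 0 called genes had a best hit. The genes listed are pear genes and assembled loci, so transcripts of the yeast may have no entry of their own. That count of 0 therefore does not show that yeast RNA was absent. Beside the fixed list and the yeasts, best hits were searched only in Phaeosphaeria, Leptosphaeria, Penicillium and Rhizophagus, singled out after the values were seen. There, 5 called genes had a best hit. Of these, 3 were listed at 0 in the yeast library, with hits in Phaeosphaeria nodorum (Pbr001779, 3.00 FPKM with water; Pbr001780, 1.49) and Leptosphaeria maculans (XLOC_039335, 2.20). The other 2 were higher with the yeast, Pbr024253 and Pbr034063 (Rhizophagus irregularis, listed at 0 and 0.339).

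For most called genes the FPKM values and the calls went together. Of the 256 called genes above 0 in both libraries, 234 had an FPKM log2 ratio within 0.5 of the value in the authors' deposited table. Many calls concerned low genes: 83 were listed at 0 only in the yeast library and 39 only in the water library, and without the genes listed at 0 the calls lower numbered 154. For XLOC_032966 the FPKM values (4.70 with water, listed at 0 with the yeast) and the log2 fold change of 2.67 in the authors' deposited table point in opposite directions.

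For some genes listed at 0, the log2 values of the authors' deposited table implied whole reads in the library where the gene was seen and 0 in the other, which gives a lower bound from a floor of 3 reads per library, adjusted for depth. The lower limit of the exact 95% interval, which covers counting error, is given beside each bound. That limit is smaller than the bound for each gene named here and is the more cautious value. The bound was at least 95.3-fold lower in the yeast library for VQ motif-containing protein 10 (Pbr025260, 299 reads with water, lower limit 77.1), at least 39.9-fold lower for CML44 (Pbr027922, 125 reads, lower limit 31.9), at least 38.9-fold lower for the biphenyl synthase relative Pbr021494 (122 reads, lower limit 31.2) and at least 12.4-fold lower for allene oxide cyclase 4 (Pbr030638, 39 reads, lower limit 9.64). The highest bound, at least 1618-fold higher, was that of XLOC_042650 (4643 reads with the yeast, lower limit 1315), an uncharacterized locus at 74.8 FPKM with the yeast, named after its value was seen. It shares its best hit in pear with the neighbouring locus XLOC_042646, taken up below. Reads may be shared between such loci, so its 0 with water may come from how reads were assigned, and this bound is uncertain. The bound was at least 226-fold higher for the PERK10-like gene Pbr000076 (650 reads with the yeast, lower limit 184) and at least 17.8-fold higher for 5'-adenylylsulfate reductase (Pbr039726, 51 reads, lower limit 13.9).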

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

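The alternatives without genes listed at 0, without hits outside pear, apple and Prunus, and without the P450-like TBP descriptions were chosen after seeing the data; the others were planned. Against 750 genes higher and 678 lower by 2-fold, a pseudocount of 0.1 gave 1347 and 1100, a pseudocount of 5 gave 274 and 243, a filter of 5 FPKM gave 470 and 382, and a 4-fold rule gave 144 and 194, each by construction, since these settings admit or remove low genes or smaller ratios. The 3 rescalings and no filter kept both counts within 1.5 times. The lowest higher count was 642 against 732 lower with totals taken without the 100 highest genes, where the larger side turned to lower. At an adjusted p of at most 0.001 and 4-fold or more in the authors' deposited table, 61 of the 143 calls higher and 159 of the 238 lower were left, and without genes listed at 0, 102 and 154. The median log2 ratio of the receptor-like kinases, 1.69, became -0.36 with no filter, since low members then enter. That of the P450 list, -1.46, became 2.01 at 5 FPKM, where low members leave and most of the higher ones are P450-like TBP loci. The jasmonate median of -1.87 became -3.60 with a pseudocount of 0.1 and -0.68 with a pseudocount of 5, and the peroxidase median of -2.07 became -4.76 and -0.75. The other medians moved by less than the interquartile range of their list: with 0.1 and 5, the receptor-like kinase median became 2.96 and 0.72, the flavonoid median of -2.67 became -4.62 and -1.68, the P450 median became -2.92 and -0.43, the biphenyl median of -4.27 became -4.95 and -2.84, the phenylpropanoid median of 1.56 became 2.60 and 0.56, and the ERF median of -1.22 became -3.68 and -0.34. Of 14 lists with at least 5 called genes, 9 kept their larger side at 5 FPKM and 11 without genes listed at 0; the PR10, WRKY and P450 lists kept it in neither, the ERF and expansin lists not at 5 FPKM. Of the 94 named genes, 73 moved by over 0.5 in log2 ratio with a pseudocount of 0.1 and 87 with a pseudocount of 5. The sign of a gene's ratio cannot turn with a pseudocount or a filter, so these settings do not test its direction. Random lists not matched on expression were not run, because only called genes have descriptions, and with a filter of 5 FPKM 5 lists were too small for a median. With 1 library per group and read totals not at hand, no interval was given on ratios of genes above 0 in both libraries, and counting error for those was not estimated. No paired analysis was possible because each group has 1 library.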

Other observations

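All groups in this paragraph were formed after the called genes were seen, and their direction is therefore not independent evidence. Sulphur genes stood together on the higher side, with 6 higher and 0 lower: the SULFUR DEFICIENCY-INDUCED 1 genes, sulfate transporter 1.2 (Pbr011127, listed at 0 with water and 0.760 FPKM with the yeast; Pbr021842, listed at 0 and 0.396), the root uptake transporter in Arabidopsis, and 5'-adenylylsulfate reductase (Pbr039726), an enzyme of sulphate assimilation. BURP domain genes were 3 higher and 0 lower (Pbr018894, 3.79 and 33.8 FPKM). On the lower side were 7 patatin-like lipase genes of 7 called (Pbr008727, 36.6 and 4.41), 6 VQ motif genes of 6 (Pbr015055, 38.8 and 4.54), whose proteins partner WRKY factors, 4 MATE efflux genes of 4, 3 EP1-like glycoprotein genes of 3 (Pbr038206, 91.5 and 7.68) and 3 acyl-activating enzyme 12 genes of 3 (Pbr033574, 10.6 and 0.377). The 7-deoxyloganetin glucosyltransferase-like genes were 1 higher (Pbr033545, 0.0801 and 5.89) and 6 lower (Pbr021702, 12.7 and 0.252). Glucose-6-phosphate/phosphate translocator 2 genes were lower and listed at 0 with the yeast (Pbr031862, 4.02 with water).

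All the tests below were chosen after the result they bear on was seen. In the order of the Pbr identifiers, 12 consecutive detected genes, from Pbr001764 to Pbr001791, were listed at 0 in the yeast library only, and the 2 of them that the authors called have best hits in the fungus Phaeosphaeria nodorum. The longest run in 1000 random orders was 5, and in the real order the longest run of genes listed at 0 in the water library only was 3. Random orders treat neighbouring genes as independent. Neighbours at low levels can drop out together, so the random orders alone do not exclude a lower depth of the yeast library. The estimated depth differed by only 1.05 times, and the 2 called genes had 77 and 50 reads with water. RNA of a fungus other than the inoculated yeast may account for the run of 12 genes. It would have been in the water library and mapped to fungal sequence held in the pear gene set. The next longest run, of 6 genes, does not decide this. Its 1 called gene (Pbr007526, 2.15 FPKM with water), described as probable endo-beta-1,4-glucanase D, has its best hit in pear. Fungal sequence held in the pear gene set could also be listed under pear, so that hit speaks neither for nor against. The levels were low, 8.27 FPKM summed over these 18 genes, and whether the yeast kept such a fungus out was not tested, since 1 wound sample per group cannot separate treatment from chance presence.

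The 37 genes called higher with best hits outside pear, apple and Prunus summed to 212 FPKM with water and 1883 with the yeast, and 28 of them are XLOC loci. Uncharacterized loci that share 1 best hit in pear lie beside some of them by identifier and are not among the 37, such as XLOC_042650 (listed at 0 and 74.8 FPKM) and XLOC_042646. The FPKM values of XLOC_042646 (1.99 and 324) make it 163-fold higher, against a log2 fold change of 2.86 in the authors' deposited table, so its size is uncertain. One common rise of ribosomal RNA carry-over in the yeast library is a candidate explanation for a part of the 37, because descriptions such as P450 like_TBP are often attached to ribosomal DNA. It was not shown for the others, among them the ATP synthase subunit beta genes Pbr011647 (0.00864 and 7.57 FPKM) and Pbr011648 (0.897 and 10.7) and the fungal hits Pbr024253 and Pbr034063. For the 29 loci with at least 5 FPKM with the yeast, the ATP synthase genes included, the interquartile range of the log2 fold changes in the authors' deposited table was 1.09, and over all 37 the highest value was 9.17 (XLOC_008163) beside a median of 3.23. The FPKM values of XLOC_008163 (0.368 and 25.3) give a smaller rise, so its size is uncertain too. RNA of the inoculated yeast read at conserved ribosomal sequence could produce unequal rises between loci. These explanations cannot be told apart here, because reads may be shared between near-identical loci and the sequences of the loci were not examined; a biological difference stays untested.

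The jasmonate, calcium and biphenyl synthase lists were lower in the yeast library in each of their called genes. Library scaling would shift all genes alike, and the median log2 ratio of the 22603 measured genes was 0.0052, so no common shift was seen. The list medians, -1.87 for the jasmonate and -4.27 for the biphenyl list, are no comparison for it. They cover called genes only, whose absolute log2 fold changes in the authors' deposited table were at least 2.66, and uncalled members were not counted. Another fungus in the water wounds could raise defence genes there and so make them lower beside it in the yeast library. With 1 library per group this cannot be told apart from an effect of the yeast on the wound response, or from a difference between the fruit sampled, and none of these was tested.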
